A study of Drosophila melanogaster with 8 samples.

How the data were processed

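RNA sequencing of 8 libraries was analysed, 2 in each of 4 groups: stage 17 embryos sired by males on 30 or 300 g/L sugar, and sperm of males on 30 or 300 g/L sugar. Per the labels, total RNA was extracted with Trizol, depleted of ribosomal RNA and made into stranded libraries. Per the submitters' processing notes, TopHat2 2.0.8, Cuffdiff 2.1.1 and the BDGP5 build were used. The annotation, the tool options and the scaling between groups are not given in the sources used here.

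The deposited data are a pair of tables, of embryos and of sperm, with identical column headers. The tissue of each table is known from its name. As a check, 47 of 50 spermatid genes reached a mean of 1 FPKM in the sperm table and 12 of 50 in the embryo table, while 84 of 141 cuticle genes did so in the embryo table and 20 in the sperm table. Per the file headers, the expression values are FPKM, with 1 deposited value per group, so the authors combined the 2 libraries of a group before deposit. The deposited p-value and its Benjamini-Hochberg adjusted form are the authors' own test of the groups for each gene. The deposited log2 fold change is the authors' logarithm of the ratio of both FPKM values. It differed by over 0.001 from the FPKM of 6 embryo genes, none of them called, and 377 embryo cells of this column hold spreadsheet errors, so every ratio was computed from FPKM instead. The number of columns of values per sample left unused is 0.

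The authors' test gave a result for 10163 of 15146 embryo genes and 6453 of 15146 sperm genes, and the deposited tables mark the others as not tested. Benjamini-Hochberg adjustment of the p-values of tested genes gave back the deposited embryo column. For sperm the deposited adjusted values are smaller than this recomputation, 0.00749 against 0.0202 at the smallest p-value, and the reason is not given in the sources used here. The smallest p-value in both tables is 5e-05, at 53 embryo and 16 sperm genes, and the p-values move in steps of that size. Since no values per library were used, no test between the groups was refitted and no replicate could be left out. Fisher's exact test, two-sided, was used across genes only to compare shares of called genes, and genes are not independent replicates. Nothing in the labels says whether the 2 libraries of a group came from separate crosses or collections, so whether the authors' p-values measure a biological or a technical spread is not known.

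Genes were called changed where the authors tested them and their adjusted p was under 0.05, without a minimum fold. Ratios on the log2 scale used FPKM plus 0.1, which understates the change of low genes. Plain ratios between FPKM values are given only where both are above 0. A value of 0 is reported as listed at 0, since no depth is known to set a floor. Lists of genes were scored by the median log2 ratio of members at a mean of 1 FPKM or more, with a 95% interval from 2000 bootstrap draws of the genes. Each median was also ranked among 10000 random lists of the same size, each member replaced by a gene from the 100 genes nearest in mean FPKM. Both describe these pools and carry no error between libraries. The count of calls in a list is given over all genes, and adjusted over the list alone.

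The 29 lists, the threshold, the rule for named genes and the first set of alternatives were fixed before the data were examined, and a list of neuroblast regulators was added later, before its values were seen. The rule named, for each tissue, the 10 largest rises and 10 largest falls among called genes with at least 1 FPKM in the higher group and a given name, with no CG or CR numbers and no small or structural RNA genes. It added up to 4 called members of each list with the smallest adjusted p, or, where none was called, the values of the 2 members with the highest mean. Where fewer than 5 genes passed in a direction, all were named with CG numbers included. This gave 69 genes in embryos and 58 in sperm, of which the text prints a part. Genes named on other grounds were chosen after their values were seen: CG31198, CG17290, CG17018, CG8173, CG18628, CecA1, Mhc, bcd, Acp70A, PebIII in sperm, betaTub85D, Cpr65Ea, Cpr51A, TwdlD, the genes of the clusters and the genes that passed only over a list alone. Symbols are those of the tables. Of the 15146 identifiers, 14278 occur in the newer BDGP6 annotation, whose names served to match list members and to identify ribosomal RNA genes, and its coordinates were used only to compare gene lengths. The start of each locus counts from 0 in the tables, since the lengths of 2209 genes then equal the BDGP6 lengths against 161 otherwise, and 1 was added. In all, 5679 genes share their locus string with another gene, and the values of such overlapping genes are less certain.

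Alternatives were adjusted p thresholds of 0.01 and 0.1, a minimum absolute log2 ratio of 1, minimum means of 0.1, 1 and 5 FPKM, pseudocounts of 0.01 and 1, ratios centred on the median of genes at 10 FPKM or more, another set of genes for the adjustment, and the removal of small and structural RNA genes. That median was -0.04 in embryos and -0.08 in sperm. The list scores were tested on simulated data made by shuffling the real ratios among genes of like expression: 6.5% of 200 unchanged embryo lists and 7.5% of 200 unchanged sperm lists fell outside the central 95% of random lists, and of 50 lists raised by 0.5 on the log2 scale 100.0% were found above that range in embryos (9940 genes) and 96.0% in sperm (9251 genes). The shuffle removes any joint regulation of list members, so it does not show how often lists of jointly regulated genes fall outside. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9. On simulated p-values, 200 changed genes were given p-values under 1e-04, and 200 of 200 passed the Benjamini-Hochberg step in both tissues. Values that small pass by construction, so this checks the arithmetic of the step and not its power.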

Results

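RNA abundance was measured by sequencing in a pair of tissues from w1118, a common laboratory strain of Drosophila melanogaster. The first is the sperm of adult males that ate food with 30 g/L (medium) or 300 g/L (high) sugar. The second is whole F1 embryos of such males at stage 17, the last stage of embryonic development before hatching. Each of the 4 groups holds 2 libraries, 8 in all. The values used here are 1 FPKM (fragments per kilobase of transcript, scaled to the sequenced fragments) per gene and group, as the authors computed it. No value per library was used here, so no spread between replicates stands beside any value, and the sequencing depth is unknown. Each tissue has its own table of 15146 genes. Among embryo values, 9940 genes had a mean of at least 1 FPKM over both groups and the authors tested 10163. Among sperm values these numbers were 9251 and 6453. Ratios below are high sugar over medium sugar, coordinates are those of the BDGP5 build, and a gene is called changed where its adjusted p in the authors' deposited table was under 0.05.

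The embryo comparison asks whether the sugar content of the father's food was accompanied by differences in the RNA of the offspring at the end of embryonic development. Genes for the larval cuticle, the chitin and protein layer that covers the body, were higher in embryos of high sugar fathers, and a small group of RNAs on the maternal and germline list was lower. That list also holds general cell cycle genes such as CycA, CycB and cdc2, so its members are not all specific to eggs or germline. Of 89 tested genes on the list of cuticle proteins and chitin, 21 rose and 0 fell in the authors' deposited table (28 and 0 when adjusted over the list alone), where an even spread of the calls over tested genes would give 0.631 rises. The median log2 ratio over the 84 members at 1 FPKM or more was 1.04 (95% bootstrap interval over genes 0.69 to 1.44), a 2.05-fold difference. This median lay above all of 10000 random lists of like expression. Of 19 tested genes on the list of maternal and germline RNAs, 0 rose and 4 fell in the authors' deposited table (0 and 7 when adjusted over the list alone), with a median log2 ratio of -0.53 (interval -1.42 to -0.18).

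In all, 82 embryo genes were called, 72 higher and 10 lower. The count was 53 at an adjusted p under 0.01 in the authors' deposited table and 52 among genes at a mean of 5 FPKM or more. Of the 72, 17 were listed at 0 in the medium sugar group. The remaining 55 had ratios from 1.97 to 33.9, with a median of 3.67. Many of the large ratios belonged to cuticle proteins, while CG17290, which is on none of the lists and was named after its values were seen, rose from 2.87 to 51.4 FPKM. Lcp65Ag1, Lcp65Ag2 and Lcp65Ag3, larval cuticle proteins, went from 1.89 to 64.2 FPKM, from 5.80 to 138 FPKM and from 6.52 to 107 FPKM, which are ratios of 33.9, 23.8 and 16.5. The adjusted p of each was 0.00959 in the authors' deposited table. They lie at 3L 6127797 to 6128370, 6126089 to 6126700 and 6123485 to 6124086, and as near-identical copies they can share reads, so their separate values are uncertain. Cpr47Eg rose from 2.22 to 36.4 FPKM (adjusted p = 0.0299 in the authors' deposited table), Cpr62Bc from 1.07 to 15.5 FPKM, TwdlB from 1.69 to 21.6 FPKM and Cpr78Cb from 0.841 to 10.4 FPKM. Abundant members rose by smaller ratios: Cpr65Ea from 192 to 620.1 FPKM, Cpr51A from 180.1 to 444 FPKM and TwdlD, of the Tweedle family of cuticle proteins, from 79.9 to 250.2 FPKM. By family, the calls were 9 of 36 tested Cpr genes, 6 of 19 Tweedle genes, 3 of 9 Lcp genes, 1 of 5 Ccp84A genes and 2 of the 20 other genes of the list. Ccp84Aa, of the list, and the serine protease yip7 were called and were listed at 0 in the medium sugar group, with 1.41 and 1.48 FPKM in the high sugar group. Eaat1, a glial glutamate transporter, was the single call among 24 tested neuron and glia markers, and rose from 2.42 to 7.06 FPKM (adjusted p = 0.0246 in the authors' deposited table).

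**Figure D1:**
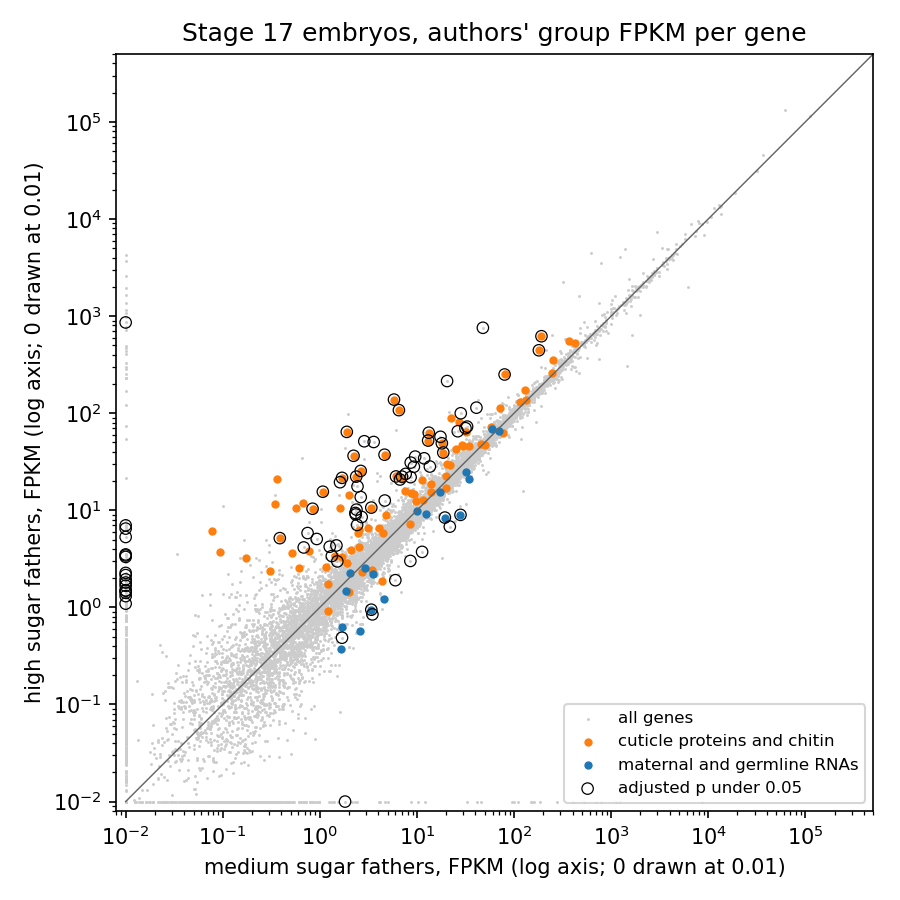
Authors' group FPKM of each gene in embryos of medium sugar fathers (horizontal, log axis) and of high sugar fathers (vertical, log axis), with values of 0 drawn at 0.01. Orange and blue points are members of the cuticle and the maternal list at a mean of 1 FPKM or more, rings mark the 82 called genes, and the line marks equal values. The orange points with rings lie above the line and the blue points with rings below it; the called genes Ccp84Aa and Cp15, with means under 1 FPKM, are drawn as rings alone.

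Among the 10 called falls were 4 members of the maternal list, osk, CycB, smg and Cp15. The smallest ratio was that of krimp, a Tudor domain gene of the piRNA pathway, which fell from 3.48 to 0.847 FPKM (adjusted p = 0.0299 in the authors' deposited table). It was the single call among 21 tested piRNA genes, and adjusted over the list alone 2 fell, krimp and CG31755. The germ plasm determinant osk fell from 3.39 to 0.946 FPKM and wisp, a cytoplasmic poly(A) polymerase, from 1.69 to 0.487 FPKM. The adjusted p of both was 0.0496 in the authors' deposited table, and neither passed when the adjustment ran over genes at 1 FPKM or more (0.054) or over all genes of the table (0.0739). The mitotic cyclin CycB fell from 28.1 to 8.97 FPKM, the securin pim from 21.8 to 6.78 FPKM, the sodium channel subunit rpk from 5.99 to 1.90 FPKM and smg, which represses maternal RNAs in the early embryo, from 19.4 to 8.41 FPKM, each with an adjusted p of 0.00959 in the authors' deposited table. Cp15, an eggshell protein, had 1.82 FPKM in the medium sugar group and was listed at 0 in the high sugar group. CG17018 (11.3 to 3.73 FPKM) and CG8173 (8.55 to 3.01 FPKM) complete the set and were named after their values were seen. The anterior determinant bcd had 1.65 and 0.376 FPKM with an adjusted p of 0.314 in the authors' deposited table, so it was not called over all genes.

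Called embryo genes often lay near each other: 26 of the 82 had another call within 20 kb, against a median of 2 and at most 12 in 1000 random sets of like expression. The random sets were matched on expression and not on gene family. Neighbouring members of a family that change together would give such an excess, so the count does not show an effect of position. The groups named here were chosen after their values were seen. Lcp65Ag3, Lcp65Ag2, Lcp65Ag1 and Cpr65Av lie within 9.59 kb at 3L 6123485 to 6133073, where 5 genes were tested. TwdlM, TwdlB and TwdlL lie within 6.53 kb at 3R 22444845 to 22451374, where 4 were tested. At 3L 16257813 to 16313554, 7 of 15 tested genes rose, CG13051, CG13068, CG13067, CG4962, CG4982, CG13063 and CG13060. All but CG13063 were listed at 0 in the medium sugar group, with 1.09 to 6.48 FPKM in the high sugar group.

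Of the 29 lists in embryos, 10 had medians above the central 95% of random lists and 5 below it, where independent genes would put 1.45 outside. Genes of energy metabolism had small positive medians: 0.13 for glycolysis and gluconeogenesis, 0.12 for the TCA cycle, 0.08 for nuclear genes of oxidative phosphorylation, 0.17 for the mitochondrial genome and 0.10 for lipid breakdown, with 0 calls in each. Muscle markers had a median of 0.19 (interval 0.10 to 0.28), haemocyte markers 0.22, detoxification genes 0.13 and digestive enzymes 0.36 (interval -0.26 to 0.82), also with 0 calls. Each of these lists with 0 calls would get at most 0.368 rises from an even spread of the calls. Adjusted over the list alone, the digestive enzymes Mal-A2 and Jon65Aiii rose. On the low side were the piRNA list at -0.46, genes of heterochromatin and silencing at -0.17, heat shock genes at -0.17 and the list of dosage compensation and sex at -0.26. Over members at 5 FPKM or more the medians of heat shock genes and of dosage compensation and sex were -0.11 and -0.13. In the list of dosage compensation and sex roX1, a noncoding RNA of the male dosage compensation complex, had 464 and 260 FPKM and roX2 had 936 and 668 FPKM, with unadjusted p-values of 0.0333 and 0.108 in the authors' deposited table and neither called.

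The lists nearest to the chromatin theme of the series title had 0 calls in embryos. An even spread of the calls would give 0.184 rises for Polycomb, 0.191 for trithorax, 0.269 for homeotic and 0.234 for heterochromatin genes, so 0 calls lies near that share. Polycomb group genes had a median of -0.09, at percentile 17.8 of random lists, and trithorax group genes had a median of -0.13, at percentile 2.52. Homeotic and other Polycomb-target regulators had a median of -0.08, at percentile 16.1. When the ratios were centred on the median of genes at 10 FPKM or more, which was -0.04, these medians came to -0.05, -0.0952 and -0.042. Of the members at 1 FPKM or more, 20 of 26 Polycomb genes, 23 of 27 trithorax genes, 22 of 36 homeotic regulators and 31 of 33 genes of heterochromatin and silencing had log2 ratios below 0. The most abundant members were sxc (151 and 154 FPKM) and pho (60.9 and 58.4 FPKM) of the Polycomb list, vtd (86.0 and 78.9 FPKM) and Nurf-38 (79.6 and 79.9 FPKM) of the trithorax list and hth (102 and 96.2 FPKM) of the homeotic list. Of the histone genes 6 reached 1 FPKM, with a median of 0.05. The medians of the remaining lists were 0.03 for insulin, TOR and hormone signalling, 0.04 for antimicrobial and immune genes (-0.0395 over members at 5 FPKM or more and -0.0066 over those at 0.1 FPKM or more), 0.03 for neuron and glia markers, -0.07 for fat body and oenocyte markers, 0.09 for spermatid genes and -0.15 for accessory gland genes. Lipid synthesis (-0.0035), cytosolic ribosomal proteins (-0.0059), mitochondrial ribosomal proteins (-0.0072) and spermatocyte regulators (-0.02) lay so close to 0 that the same centring turned their sign. None of these lists but the neuron and glia markers had a call.

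The sperm comparison asks whether the RNA of the males' sperm differed with the sugar content of their own food. The list of spermatid and sperm structure genes and the list of accessory gland and ejaculatory duct genes had medians higher in the high sugar group, with few members called. Of 39 tested spermatid genes, 3 rose and 0 fell in the authors' deposited table (12 and 0 when adjusted over the list alone), where an even spread of the calls would give 0.127 rises. Over the 47 members at 1 FPKM or more the median log2 ratio was 1.22 (interval 0.90 to 1.39), a 2.34-fold difference, and lay above all of 10000 random lists. Of 20 tested accessory gland and ejaculatory duct genes, 1 rose and 0 fell in the authors' deposited table (1 and 0 when adjusted over the list alone), with a median of 1.13 (interval 0.66 to 2.05) over 26 members.

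In all, 22 sperm genes were called, 21 higher and 1 lower. The leucyl aminopeptidases S-Lap1 and S-Lap7, abundant sperm proteins, rose from 77.4 to 229 FPKM and from 52.6 to 158 FPKM, and loopin-1, a related sperm protein, from 51.6 to 155 FPKM, each with an adjusted p of 0.00749 in the authors' deposited table. Adjusted over the list alone the male-specific transcript Mst87F (106 to 264 FPKM), ocn (76.3 to 189 FPKM) and dj (17.1 to 51.7 FPKM) also rose. The testis tubulin betaTub85D had 25.8 and 39.2 FPKM and was not called. Dup99B, a seminal fluid peptide of the ejaculatory duct, rose from 254 to 778 FPKM (adjusted p = 0.0314 in the authors' deposited table, 0.0849 when recomputed over tested genes). Of the same list Acp70A, the sex peptide, had 11.1 and 49.8 FPKM and PebIII 248 and 207 FPKM, and neither was called. Pen, an importin alpha, rose from 23.5 to 62.0 FPKM (adjusted p = 0.037 in the authors' deposited table, 0.0968 when recomputed over tested genes). The antimicrobial peptide gene CecA2, at 3R 26037878 to 26038291, was called and listed at 0 in the medium sugar group with 39.0 FPKM in the high sugar group. Its neighbour CecA1 had 1.36 and 251 FPKM with an unadjusted p of 0.246 in the authors' deposited table. The cytochrome P450 gene Cyp6a18, which is on none of the lists, was called and listed at 0 and 6.15 FPKM.

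The single called fall in sperm was Tsf1, a transferrin secreted by the fat body, which went from 429 to 107 FPKM (adjusted p = 0.00749 in the authors' deposited table) and lies on X at 18281965 to 18284377. Adjusted over the list alone, the oenocyte gene Cyp4g1 rose (8.29 to 29.9 FPKM) beside the fall of Tsf1 among 9 tested fat body and oenocyte markers, whose median was 0.08 over members at 1 FPKM or more and -0.06 over those at 0.1 FPKM or more. Muscle RNA was abundant in both sperm groups, with Mhc at 313 and 307 FPKM and Act57B at 926 and 943 FPKM, and the muscle list had a median of -0.09 (interval -0.14 to -0.03), which came to -0.0095 when the ratios were centred. Neuron and glia markers had a median of 0.0032, which came to -0.0777 over members at 5 FPKM or more, and haemocyte markers of -0.08, and the latter turned sign when centred. A single gene, CG18628, made up 31.1% and 29.4% of the summed FPKM of the medium and high sugar sperm groups. In the same groups the median FPKM of the muscle list was 136 and 134, above the 11.8 and 21.7 of the spermatid list. The lists hold different genes, so these values do not give the share of RNA from each tissue. The deposited adjusted p of sperm genes is smaller than the table's own p-values give: recomputed over the tested genes, 16 of the 22 calls remained, and Dup99B (0.0849) and Pen (0.0968) did not.

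**Figure D2:**
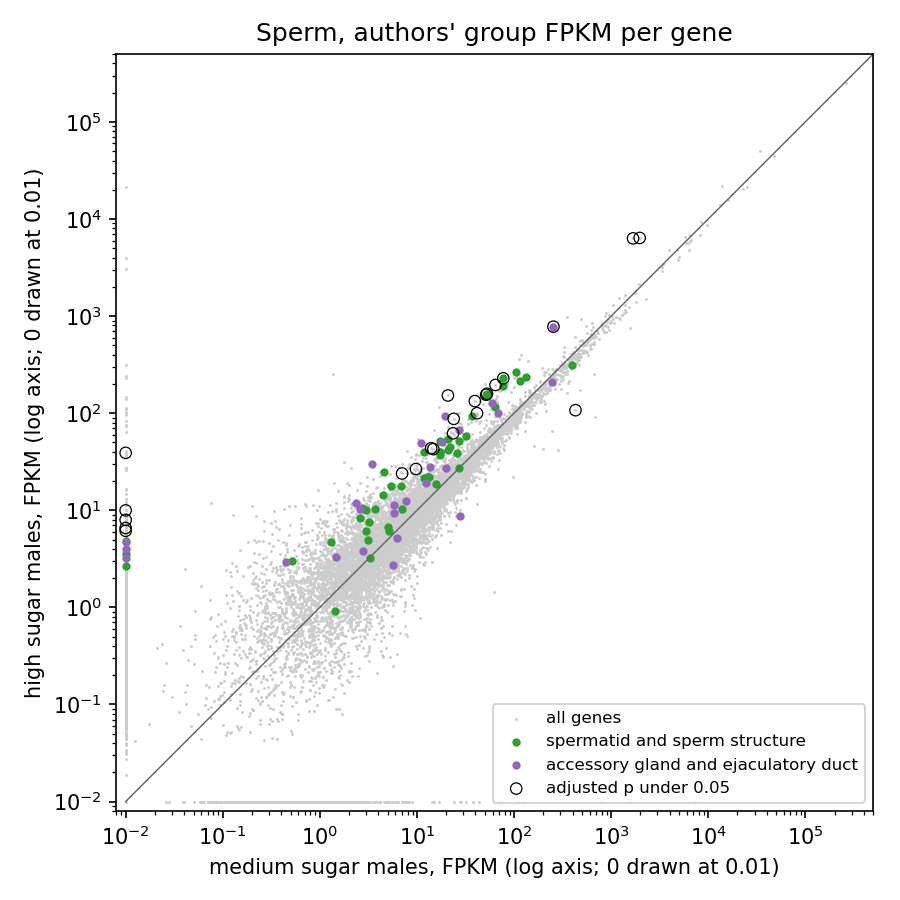
Authors' group FPKM of each gene in sperm of medium sugar males (horizontal, log axis) and of high sugar males (vertical, log axis), with values of 0 drawn at 0.01. Green and purple points are spermatid and accessory gland list members at a mean of 1 FPKM or more, rings mark the 22 called genes, and the line marks equal values. Of the 47 green points 44 lie above it.

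Of the other sperm lists, glycolysis and gluconeogenesis had a median of 0.08, nuclear genes of oxidative phosphorylation 0.04 and cytosolic ribosomal proteins -0.06, which were above the central 95% of random lists of like expression. These medians came to 0.16, 0.12 and 0.02 when the ratios were centred. Adjusted over the list alone, the aldolase gene CG5432 rose from 8.03 to 27.2 FPKM. Below the central 95% were mitochondrial ribosomal proteins at -0.27, heat shock genes at -0.31, lipid breakdown genes at -0.26 and detoxification genes at -0.19, with 0 calls in each. At an even spread of the calls, each would hold at most 0.199 rises. Over members at 5 FPKM or more the median of mitochondrial ribosomal proteins was -0.14, and that of detoxification genes was -0.11 when centred and -0.10 over members at 0.1 FPKM or more. Polycomb group genes had a median of -0.12, trithorax group genes of 0.16, heterochromatin and silencing genes of -0.14, homeotic and Polycomb-target regulators of -0.16 and histone genes of -0.19, all with 0 calls. Centred, these medians came to -0.04, 0.24, -0.06, -0.08 and -0.11. Over members at 5 FPKM or more the Polycomb median was -0.015. Each of these lists would get at most 0.0748 rises from an even spread of the calls. The medians were -0.11 for lipid synthesis, -0.08 for insulin, TOR and hormone signalling, -0.14 for digestive enzymes, -0.17 for cuticle genes, 0.26 for piRNA genes, 0.19 for spermatocyte regulators and 0.17 for dosage compensation and sex. Over members at 0.1 FPKM or more the sign turned for cuticle genes (0.77), homeotic regulators (0.28), digestive enzymes (0.38), maternal RNAs (0.56) and piRNA genes (-0.0235), and over members at 5 FPKM or more for dosage compensation and sex (-0.0425). The lists of the TCA cycle (-0.01), the mitochondrial genome (-0.06), antimicrobial and immune genes (-0.06) and maternal RNAs (-0.05) turned sign when centred. Of the lists in these sentences the antimicrobial list alone had a call, CecA2.

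**Figure D3:**
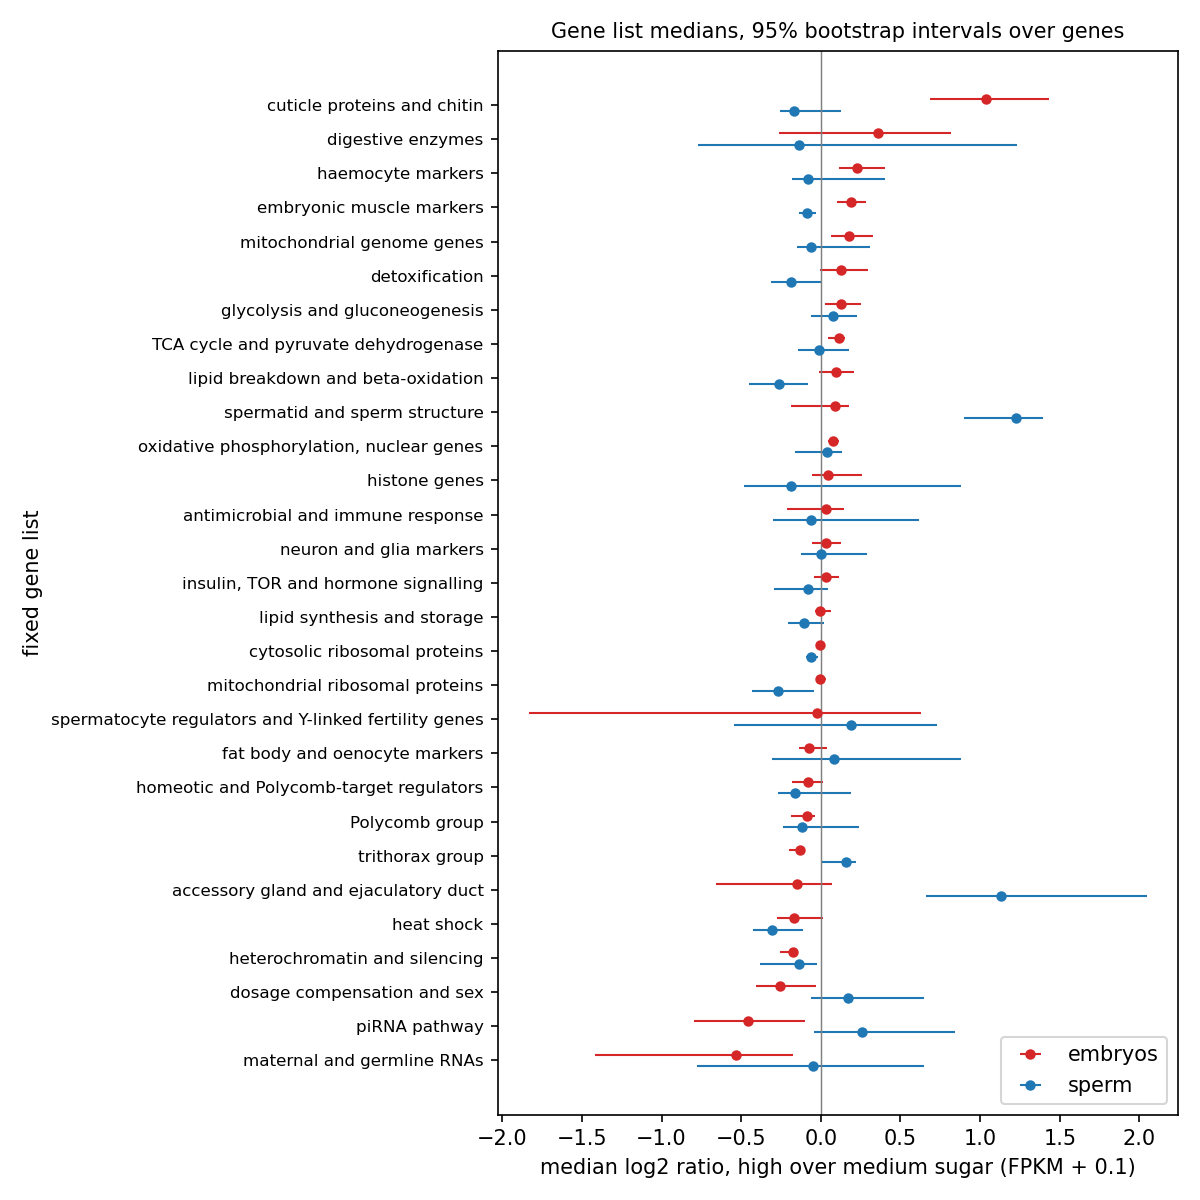
Median log2 ratio of high over medium sugar (horizontal, FPKM plus 0.1) for each of the 29 gene lists (vertical), in embryos (red) and sperm (blue). Points are medians over members at a mean of 1 FPKM or more and bars are 95% bootstrap intervals over genes, which do not cover the spread between libraries. The cuticle list stands at 1.04 in embryos and -0.17 in sperm, and the spermatid list at 0.09 in embryos and 1.22 in sperm.

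The last comparison sets the embryo ratios beside the sperm ratios, to ask whether the same RNAs differed in the sperm of fed males and in embryos sired by fed males. Across 7709 genes at 1 FPKM or more in both tissues, Pearson's r was -0.075 (bootstrap interval over genes -0.194 to 0.041) and Spearman's rho was 0.0029 (interval -0.0216 to 0.0258). Over the 23 of these genes called in either tissue r was 0.21. Those 23 genes were selected by calls on the same values and no interval is given, so no agreement between tissues is read from 0.21. Genes are not independent replicates, so these values describe the tables only. The tissues share no control libraries. Of 5716 genes tested in both tissues, 11 were called higher in embryos and 6 in sperm, with 1 shared, where independent lists would share 0.0115. The shared gene was CG31198, at 3R 17580046 to 17583490, which rose from 4.66 to 12.6 FPKM in embryos and was listed at 0 and 9.97 FPKM in sperm. No gene was called in opposite directions. Whether a gene list differed between the tissues in its response was not tested.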

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

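The alternatives without genes listed at 0, without shared loci and without unplaced and heterochromatic sequence, the adjustment recomputed over tested genes, and list medians over tested members alone or without members listed at 0 were chosen after the data were seen. The embryo count of 82 was 53 at an adjusted p under 0.01, with 5 lower, and 52 at a mean of 5 FPKM or more, with 47 higher and 5 lower; both settings can only remove genes. The lower sperm count was 2 at an adjusted p under 0.1, by the looser threshold. Other total counts ranged from 64 to 92 in embryos and from 16 to 32 in sperm. Without genes listed at 0 in either group they were 64 and 17. Centred on the median of genes at 10 FPKM or more, the embryo medians were 0.12 for oxidative phosphorylation, -0.10 for trithorax, -0.14 for heterochromatin and 0.031 for cytosolic ribosomal proteins. The sperm medians were 0.24 for trithorax, -0.0095 for muscle and 0.021 for cytosolic ribosomal proteins, the last with its sign turned although it lay outside the central 95% of random lists, and each moved by the centring itself. With members at 0.1 FPKM or more the sperm medians were 0.28 for homeotic regulators and 0.77 for cuticle genes, and the cause was not tested. Of 402 list medians under other settings, 22, in 18 lists and tissues, had another sign than reported: 10 when centred, 7 with members at 0.1 FPKM or more, 3 with members at 5 FPKM or more, and 1 each over tested members and without members listed at 0. Many medians near 0, the chromatin lists in sperm among them, also changed in size when centred. Pearson's r between tissues was 0.21 over the 23 genes at 1 FPKM or more in both and called in either, and the cause was not tested. Those genes were selected by calls on the same values. Of 381 named ratios 16 moved, all under another pseudocount, which cannot turn a sign. Centring turned the sign of negative ratios smaller in size than the centring median. Among them were Idh in embryos (-0.03 against a median of -0.04) and RpL41 in sperm (-0.05 against -0.08). Of 78 recomputed adjusted p-values 10 no longer passed: osk and wisp (0.054 to 0.0739), Dup99B (0.0849 to 0.199) and Pen (0.0968 to 0.227). No paired analysis was possible because the labels share replicate numbers but the tables hold no values per library. For the same reason other pseudocounts on replicate values, a test on counts with other size factors, leaving out a replicate and a replicate block were not run. Depth is unknown, so no floor was set for values of 0.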

Other observations

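All tests in this part were chosen after the results were seen except that of neuroblast regulators and the Fisher exact test over all genes listed at 0. Called noncoding genes of repeated or unplaced sequence were chosen after their values were seen. In sperm CR40677, which the newer annotation names a 2S ribosomal RNA pseudogene, rose from 1681 to 6313 FPKM, and CR41583 from 1966 to 6375 FPKM. Other abundant genes of ribosomal RNA sequence in sperm were not called, with 23010.1 and 20519 FPKM for CR41609, 6432 and 5910.0 FPKM for CR41602 and 956 and 1020.4 FPKM for CR41548. In embryos CR41544, on unplaced sequence, rose from 47.7 to 758 FPKM, CR40640 from 28.3 to 99.8 FPKM and CR41590 from 0.682 to 4.14 FPKM. CR41609, named a 28S ribosomal RNA pseudogene, had 1221 and 4053 FPKM in embryos with an adjusted p of 0.146 in the authors' deposited table. In embryos CR41602 had 211 and 449 FPKM, CR41548 1104 and 1595 FPKM and CR40677 5355 and 5584 FPKM, and none of these was called. The median log2 ratio over genes of unplaced sequence was 0.09 in embryos (54 genes, interval 0.01 to 0.25) and 0.30 in sperm (50 genes, interval 0.05 to 0.65). Genes of the heterochromatic arms (2LHet to YHet) had a median of -0.17 in sperm (47 genes, interval -0.34 to -0.04). In embryos that median was -0.01 (60 genes, interval -0.06 to 0.05). Genes of chromosome X had medians of -0.03 in embryos and -0.04 in sperm. Genes of chromosome 4 had a median of -0.21 in sperm (69 genes, interval -0.29 to -0.13) and 0.01 in embryos (80 genes). The embryo call CG31233, at 0.747 and 5.83 FPKM, lies beside CG31198, which was called in both tissues. The gene of the minor spliceosome snRNA:U6atac:29B was called in embryos and listed at 0 and 860 FPKM.

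The rise of cuticle genes and fall of maternal RNAs in embryos of high sugar fathers could come from the make-up of the embryo pools. A smaller share of unfertilised eggs, or of eggs arrested before muscle forms, would raise late tissues alike. The muscle median was 0.188 (interval 0.10 to 0.28), below the cuticle interval of 0.69 to 1.44. This argues against such eggs as the cause for the cuticle genes. Embryos arrested later can carry muscle RNA, so the test does not cover them. For the maternal RNAs, with a median of -0.535, a smaller share of unfertilised or arrested eggs stays open. No list here separates eggs from an embryo's own germline or its dividing cells. Older embryos in the high sugar pool also stay open, since the median of 13 neuroblast regulators was -0.011 with an interval of -0.20 to 0.16 that includes changes in both directions. The fathers' sugar, which the design names, stays open as well and was not tested.

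The higher medians of spermatid and accessory gland genes in the sperm of high sugar males might reflect the tissues carried along with the sperm. A lower share of muscle RNA alone would raise every other cell type alike. Instead, 30 fat body, haemocyte and neuron markers had a pooled median of 0.011 (interval -0.11 to 0.21), below the spermatid interval of 0.90 to 1.39. This argues against a lower share of muscle RNA alone. A lower share of all body tissue carried along stays open, since these markers would then fall with muscle and the test cannot decide. More RNA of the whole male reproductive tract stays open: the spermatid and accessory gland medians differ by 0.093, less than their intervals, and no list here separates the tract from sperm. An effect of sugar on these RNAs stays open and was not tested.

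A value of 0 in one group may make the authors' test call a gene more easily: in embryos 18 of 51 tested genes listed at 0 in one group were called, against 1 of 21 tested genes with both values above 0, an absolute log2 ratio of at least 3 and at most 10 FPKM (Fisher's exact test, two-sided, p = 0.00762). Limited to at most 10 FPKM, 17 of 25 genes listed at 0 were called (Fisher's exact test, two-sided, p = 1.04e-05). In sperm 5 of 66 were called against 0 of 30 without that limit (Fisher's exact test, two-sided, p = 0.321) and 4 of 33 with it (Fisher's exact test, two-sided, p = 0.115). By direction, 17 of 35 embryo genes listed at 0 in the medium sugar group were called and 1 of 16 listed at 0 in the high sugar group, a difference that a 0 as such does not predict and that was not tested, and true absence in the group listed at 0 also stays open, untested.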
